A study of Homo sapiens with 8 samples.

How the data were processed

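Chromatin immunoprecipitation (ChIP) with an antibody against the HA tag was read on NimbleGen promoter tiling arrays (ChIP-chip). Per the labels, the cells were LNCaP, a human prostate cancer line, carrying a lentivirus for either HA-tagged HOXC6 with YFP or YFP alone, and they were sorted for YFP. Each of the 2 groups had 2 biological replicates, and each replicate was hybridised to both arrays of a set of 2 designs, which gave 8 arrays. Per the labels, Cy3 carried the anti-HA immunoprecipitate (IP) and Cy5 the input DNA on every array, so no dye was swapped. The array that the labels number 1 carries the second design of the set in its file header, and array 2 the first; the labels' numbers are used here.

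The deposited scanner files hold 1 intensity per probe and channel, at 532 nm for Cy3 and 635 nm for Cy5. Per the file headers they were extracted with NimbleScan 2.3.22 from a design on genome build HG18. No background subtraction or normalization is recorded there, and the mismatch column is 0 throughout. The authors' series tables hold a score per probe. Set against the scanner files, that deposited score correlated at 1 with the log2 ratio of Cy3 over Cy5 on each array, and it had a mean of 0 and an SD of 1 over all probes of the array. Direction, centring and scale of the tables were therefore settled, and they served as an alternative. Column medians lay between 0.136 and 0.234. How DNA was sheared and amplified before labelling is not given in the sources used here.

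The arrays tiled 23047 promoter regions, 11630 on array 1 and 11417 on array 2, with 757904 probes at a median spacing of 100 bp. A region held a median of 31 probes on array 1 and 32 on array 2, and 9911 regions were 4250 bp long. Another 10000 probes of random sequence per array measured background and entered no region. Median signal over tiled probes ran from 783.3 to 1386 in the IP channel and from 549.8 to 1288 in the input channel. The share of tiled probes above the 95th percentile of the random probes was 15.8% to 38.0% in the IP channel and 32.3% to 54.8% in the input channel. At most 65 tiled probes per array and channel were saturated. The number of arrays limits the precision. Each of the 8 arrays was a slide of its own and the headers give a single day, so neither could be fitted as a batch.

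The value of a probe was the log2 ratio of IP over input, centred on the median of its array, with no loess or quantile step because ChIP signal can truly shift one way. The value of a region was the mean over its probes. HOXC6-HA was compared with YFP control in limma 3.58.1 under R 4.3.3 (lmFit and eBayes), with 2 samples against 2 and each array design fitted separately. In the same fit each group mean was tested against 0, the median of the array. P-values were adjusted by the Benjamini-Hochberg method over all 23047 regions, with a threshold of 0.05. A HOXC6-specific region had to pass both tests on the higher side. Groups were fitted without the replicate number, since nothing in the labels says that equal numbers mark a shared culture or day. The labels call the replicates biological.

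Peak-shaped signal was sought in each sample on its own with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Probes above the 95th percentile of their array were counted in a window of 500 bp around each probe, and a window was called at a one-sided hypergeometric p of 0.0001 or less. That p runs over probes and describes 1 array, not a group. A region counted for HOXC6-HA where both HOXC6-HA samples and neither YFP control sample held a called window. The mirror count, both YFP control samples and neither HOXC6-HA sample, was planned as the background. It is a clean one only if samples share signal through their group alone, which YFP control 1 puts in doubt below. Figures were drawn with matplotlib 3.10.9.

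Both procedures were tested on simulated data. Region SDs were taken as observed but shuffled among regions, with normal noise. Limma then called 50 of 50 regions changed by a log2 difference of 4 and 42 of 50 at 2. It called 20 of 50 at 1, 0 of 50 at 0.5 and 1 unchanged region. All changed regions were planted together, which eases the adjusted threshold. Fewer changed regions would be called less often at the same size. On permuted ratios of 1 array of 11630 regions, the window test found 196 of 196 regions with a planted run of 5 raised probes and called 5 others. The planted runs were higher than most runs found below, whose median height in the lower sample of a pair was 1.46 and 1.92. Permuting also breaks the likeness of neighbouring probes, so neither result carries over to the arrays as measured.

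Named regions followed a rule set before the data were examined. These were the 15 highest and 10 lowest differences past the threshold, filled from the highest and lowest moderated t where too few passed, and the 5 regions with the highest mean in each group. The alternatives set before the data were examined covered background correction, loess, quantile and Tukey centring, 3 other definitions of the region or its value, the authors' score, a filter on dim probes, 2 variance models, the replicate number as a block, single probes, each sample left out in turn, and settings of the window test. The files name regions by coordinates only. The gene table at hand is on another genome build, so no region was given a gene name, and no coordinate was converted. The planned tests of gene lists (HOX genes and cofactors, signalling, androgen response and others), the check of HOXC6 sequence in input DNA, and the named genes HOXC6, MME and IGFBP3 were therefore not run.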

Results

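The data compare anti-HA ChIP from LNCaP cells that carry HA-tagged HOXC6, a homeodomain transcription factor, with the same ChIP from LNCaP cells that carry YFP alone. The control cells have no tagged protein, so their signal serves as the background of the antibody and the procedure. Peak-shaped signal of YFP control 1 coincided with that of HOXC6-HA 1 in 276 regions, of YFP control 2 in 189 and of HOXC6-HA 2 in 57. The design asks which promoters hold more IP signal with HOXC6-HA than without it. Each group had 2 biological replicates, each on both arrays of the promoter set, and 23047 promoter regions were measured in all 4 samples. Values below are log2 ratios of IP over input, relative to the median of the array, and coordinates are on HG18.

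No promoter region differed between HOXC6-HA and YFP control at an adjusted p of 0.05 in limma, and so no region met the definition of HOXC6-specific in this fit, which left the replicate number out. The smallest adjusted p was 0.281. On simulated data the same fit called 42 of 50 regions changed by 2, 20 of 50 at 1 and 0 of 50 at 0.5. Smaller differences could therefore be missed. Changed regions of several sizes were planted together there, which eases the adjusted threshold. Larger differences in few regions could thus be missed too. At an unadjusted p under 0.05, 410 regions were higher in HOXC6-HA and 885 were lower. This balance depended on the setting: it was 986 higher and 1008 lower after loess, 902 and 884 after quantile normalization and 788 and 680 with the best window of 5 probes. It was 902 and 3055 without YFP control 1, 1002 and 962 without YFP control 2, 466 and 681 without HOXC6-HA 1, and 105 and 164 without HOXC6-HA 2. The difference was under 0.25 in size in 90.1% of regions, and it exceeded 1, a doubling or halving, in 2 regions on the higher side and 8 on the lower side. In 3155 regions both HOXC6-HA samples lay above both YFP control samples and in 4788 they lay below, together 34.5% of all regions, where chance gives 33.3%. The SD of the difference over regions was 0.158 and the median standard error of 1 region's difference was 0.117. Some alternatives gave calls. Among single probes, 30 of 757904 were higher and 626 lower, in 28 and 389 regions. There were 2 higher and 13 lower regions after quantile normalization and 4 lower with an intensity trend in eBayes. Normexp and loess gave 1 lower region each. With the replicate number as a block there were 5 higher and 9 lower regions and 1 HOXC6-specific region, though equal numbers are not shown to mark pairs. Some fits with 1 sample left out also gave calls. The lone sample of a group is then assumed to vary like the other group, so those calls rest on 1 sample of that group.

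**Figure D1:**
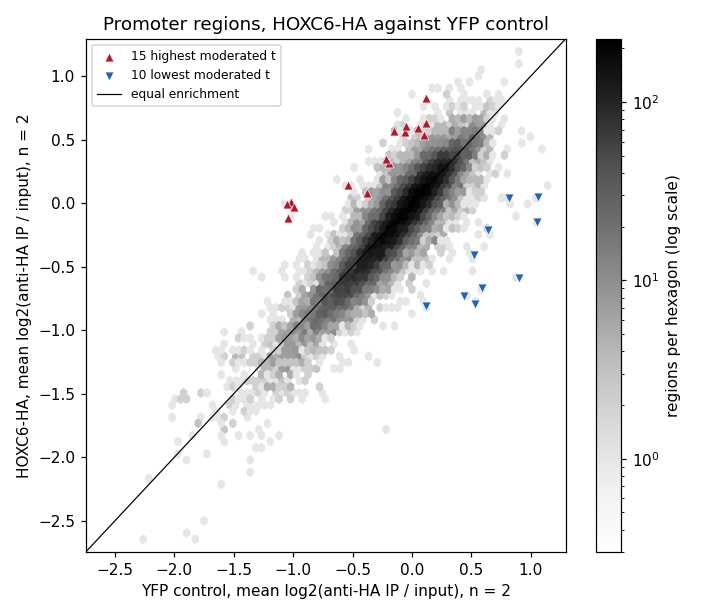
Mean log2 ratio of IP over input per promoter region in HOXC6-HA (vertical axis) against YFP control (horizontal axis), with 2 samples per group; shading gives the number of regions per hexagon on a log scale, and triangles mark the 15 regions with the highest and the 10 with the lowest moderated t. The regions lie along the line of equal enrichment, and no marked region passed the adjusted threshold.

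The regions that stood farthest from equality were lower in HOXC6-HA. None passed the threshold, and they were taken by moderated t. On chromosome 6, from 31907123 to 31911439, the log2 ratio was 0.90 ± 0.31 (SD, n = 2) in YFP control and -0.59 ± 0.10 in HOXC6-HA, a difference of -1.48 (SE 0.15, limma adjusted p = 0.281). On chromosome 17, from 388444 to 392694, the values were 0.53 ± 0.10 and -0.79 ± 0.19, a difference of -1.32. On chromosome 16, the region from 87756791 to 87761041 differed by -1.26 and the region from 65583531 to 65587781 by -1.17. On chromosome 15, from 28333253 to 28337503, YFP control measured 1.05 ± 0.12 and HOXC6-HA -0.15 ± 0.07, a difference of -1.20. On chromosome 12, from 132264567 to 132268967, the values were 1.06 ± 0.02 and 0.05 ± 0.05. These 6 regions shared the adjusted p of 0.281. The other 4 of the 10 lowest lay on chromosomes 6, 10, 15 and 17, with differences of -0.93 to -0.78 and adjusted p up to 0.545. The chromosome 16 region at 87756791 and the chromosome 15 regions at 28333253 and 99215798 also counted in the mirror case of peak-shaped signal. Both YFP control samples and neither HOXC6-HA sample held a called window there. Signal that YFP control 1 shared with other samples, described below, may thus bear on these differences. All 10 had both HOXC6-HA samples below both YFP control samples, but choosing regions by the lowest moderated t favours this. Of these 10 regions, 9 passed the threshold in at least 1 alternative setting. None changed sign, but without overlap of the groups, leaving out 1 sample could not reverse a difference. With the median over probes the 10 differences shrank to -0.68 to -0.22, all with adjusted p of 0.999 in limma. With the best window of 5 probes they were -3.94 to -0.71. The chromosome 15 region at 28333253 was called with quantile normalization, with an intensity trend and with the replicate block, at -1.29, -1.20 and -1.20. Its difference was -0.45 with the median over probes and -3.94 with the best window of 5 probes, and neither passed.

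The 15 regions with the highest moderated t differed by 0.44 to 1.03, with adjusted p of 0.793 to 0.799. The 4 largest differences among them lay on random contigs of chromosomes 21 and 4, which are sequence of a chromosome with no set position on it. There the signal stood below the median of the array in YFP control and near it in HOXC6-HA. On the chromosome 21 contigs the region from 163875 to 168170 measured -1.02 ± 0.33 (SD, n = 2) in YFP control and 0.01 ± 0.07 in HOXC6-HA, a difference of 1.03 (SE 0.17). The region from 1383659 to 1387909 also differed by 1.03, and the region from 1533045 to 1537295 by 0.91. On the chromosome 4 contigs the region from 554292 to 558587 differed by 0.96. Regions that lay above the array median in HOXC6-HA included chromosome 14 from 19361947 to 19366197, at 0.83 ± 0.12 against 0.12 ± 0.14, and chromosome 22 from 35355863 to 35360119, at 0.57 ± 0.26 against -0.15 ± 0.09. Chromosome 8 from 120032712 to 120036992 measured 0.56 ± 0.06 against -0.06 ± 0.22, and chromosome 1 from 89363617 to 89367887 measured 0.54 against 0.10. Of the 15, 4 passed the threshold in at least 1 alternative setting and none changed sign.

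By the mean over a region, enrichment over input was common in both groups and covered largely the same promoters. In limma, 2999 regions lay above the array median in HOXC6-HA and 2571 in YFP control, and 8492 and 7186 lay below it. The groups shared 1832 enriched regions and 6449 depleted regions. Independent lists of these lengths would share 335 and 2648, but these lists were not independent by design. Each region had 1 variance for both tests, and the ratio fell with the input level in both groups. The highest HOXC6-HA means were 1.19 ± 0.41 (SD, n = 2) on chromosome 20 from 3842736 to 3846986, 1.12 ± 0.02 on chromosome 12 from 54008251 to 54012501 and 1.06 ± 0.49 on chromosome 15 from 74090723 to 74095342. Chromosome 15 from 56771866 to 56776121 measured 0.99 ± 0.34 and chromosome 14 from 44045458 to 44049708 measured 0.96 ± 0.12. The same 5 regions measured 0.49 to 0.89 in YFP control. The highest YFP control means were 1.14 ± 0.67 on chromosome 9 from 99746180 to 99750455, 1.08 ± 0.15 on chromosome 11 from 102570409 to 102575942 and 1.00 ± 0.17 on chromosome 17 from 10264997 to 10269247. The chromosome 12 and chromosome 15 regions at 132264567 and 28333253 had the other 2 of the 5 highest means. The count for HOXC6-HA was 300 without HOXC6-HA 2 and 765 without HOXC6-HA 1, and that for YFP control was 1651 without either HOXC6-HA sample. With the best window of 5 probes as the value of a region, limma called 0 regions in HOXC6-HA and 239 in YFP control. The smallest adjusted p in HOXC6-HA was 0.0665, and at an unadjusted p under 0.05 there were 10758 and 9101. That window was picked for the highest mean over all samples, so a value above 0 was built in. These counts are therefore no measure of enrichment.

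Enriched promoters were those with little input signal. Among the lowest of 4 equal bins of regions by input signal, 46.6% were enriched in HOXC6-HA and 41.7% in YFP control. In the highest bin it was 0.1% in each. Across regions, the ratio fell with the input level on all 8 arrays, with Pearson's r from -0.923 to -0.776. Input is the denominator of the ratio, and regions are not independent replicates. Chromosomes differed in the same way. Enriched regions made up 25.1% of chromosome X in YFP control and 26.3% in HOXC6-HA, where median input signal was low, and 2.5% and 3.6% of chromosome 22, where it was high. Chromosome 19 had 3.1% and 4.2%, and chromosome 13 had 24.0% and 28.7%. After loess normalization within each array, which removes a trend of the ratio on intensity, 206 regions were past the threshold in HOXC6-HA and 72 in YFP control, and 4 of the 5 regions with the highest HOXC6-HA means were not among them. The means of these 4 were 0.96 to 1.19 before loess and 0.80 to 1.21 after it, where limma gave adjusted p of 0.0502 to 0.105. The 5 regions with the highest YFP control means did pass after loess, with adjusted p of 0.0160 to 0.0435. Without the dimmest 10% of probes the counts were 1730 and 1224.

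**Figure D2:**
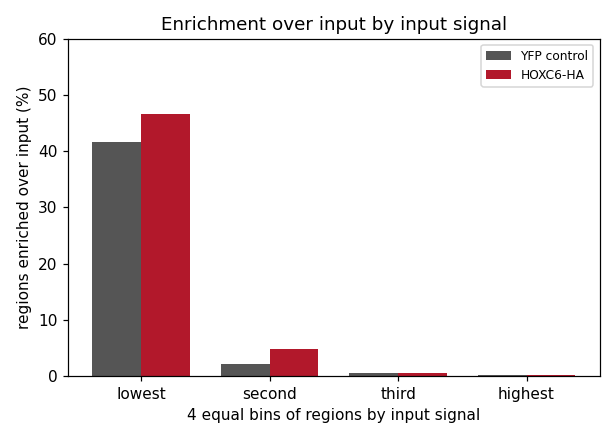
Share of promoter regions enriched over input at an adjusted p of 0.05 (vertical axis, percent) in YFP control and HOXC6-HA, by 4 equal bins of the regions' input signal (horizontal axis). Enrichment lies mostly in the lowest bin, at 41.7% and 46.6% of regions, and is 0.1% in the highest bin of both groups.

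Peak-shaped signal called in both samples of 1 group and in neither of the other stood in similar numbers of regions. A sample without a call could still hold weaker signal there. A called window stood in both HOXC6-HA samples and in neither YFP control sample in 134 regions, and in the mirror case, both YFP control samples and neither HOXC6-HA sample, in 126. The largest set belonged to a pair across the groups: 204 regions had the signal in YFP control 1 and HOXC6-HA 1 only. The other mixed pairs had 6, 16 and 41 regions. YFP control 1 thus shared signal with both YFP control 2 and HOXC6-HA 1. Such sharing can raise the mirror count, and it takes signal of HOXC6-HA 1 out of the HOXC6-HA count. Setting 134 against 126 is therefore no comparison of signal with a clean background. Without YFP control 1 the count for HOXC6-HA was 151. Of 2321 regions called in any sample, 1707, or 73.5%, were called in 1 sample only and 26 in all 4. Called regions numbered 997 in YFP control 2, 618 in HOXC6-HA 1 and 901 in HOXC6-HA 2, and YFP control 1 had the fewest. A stricter window p of 1e-06 left 19 regions for HOXC6-HA and 34 for YFP control, and loess gave 242 and 183. Asking for the signal in a single HOXC6-HA sample gave 796 regions without HOXC6-HA 1 and 319 without HOXC6-HA 2; for YFP control it gave 870 without YFP control 1 and 242 without YFP control 2.

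**Figure D3:**
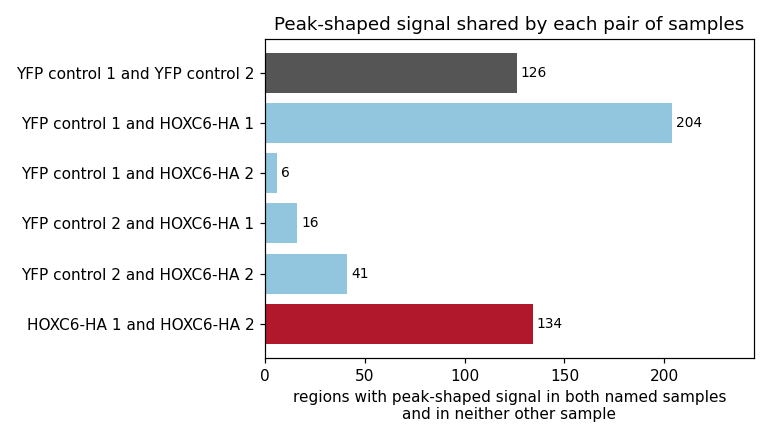
Number of promoter regions with peak-shaped signal in both samples of a pair and in neither other sample (horizontal axis), for each of the 6 pairs of samples; the bars of the HOXC6-HA pair and the YFP control pair are red and dark grey. The HOXC6-HA pair has 134 regions and the YFP control pair 126, both below the 204 of YFP control 1 with HOXC6-HA 1.

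The regions of the HOXC6-HA pair held short runs of raised probes. The following regions were chosen after their values were seen, from those that stood highest by the mean of their best 5 neighbouring probes in the lower sample of the pair, and their coordinates are the positions of the first and last of these probes. On chromosome X, from 47750377 to 47750777, those probes averaged 2.87 and 4.87 in HOXC6-HA 1 and 2 and -0.03 and -0.94 in YFP control 1 and 2. On chromosome 12, from 106549938 to 106550338, they averaged 2.71 and 3.27 against -0.79 and 1.13, and on chromosome 14, from 61298119 to 61298519, 2.89 and 3.45 against 1.48 and 0.85. Chromosome 12 from 107481711 to 107482311 had the highest signal, 3.31 and 3.75, but also 2.07 in YFP control 1. The YFP control pair had runs of the same kind. On chromosome X, from 67782557 to 67782957, the probes averaged 3.45 and 3.73 in YFP control 1 and 2 against 0.64 and 0.03 in HOXC6-HA 1 and 2, and on chromosome 19, from 12708686 to 12709086, 3.32 and 3.34 against -0.25 and -0.18. The median height in the lower sample was 1.46 over the 134 HOXC6-HA regions and 1.92 over the 126 YFP control regions. In 32 of the former and 55 of the latter it exceeded 2. None of the 134 and none of the 126 regions differed between groups over the whole region. The lowest adjusted p in limma was 0.793 and 0.281 there. That test cannot decide on the runs, since a mean over the region dilutes a few raised probes. The chromosome X region with the run at 47750377 differed by 0.57 as a whole, and in the simulation limma called 0 of 50 regions changed by 0.5.

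**Figure D4:**
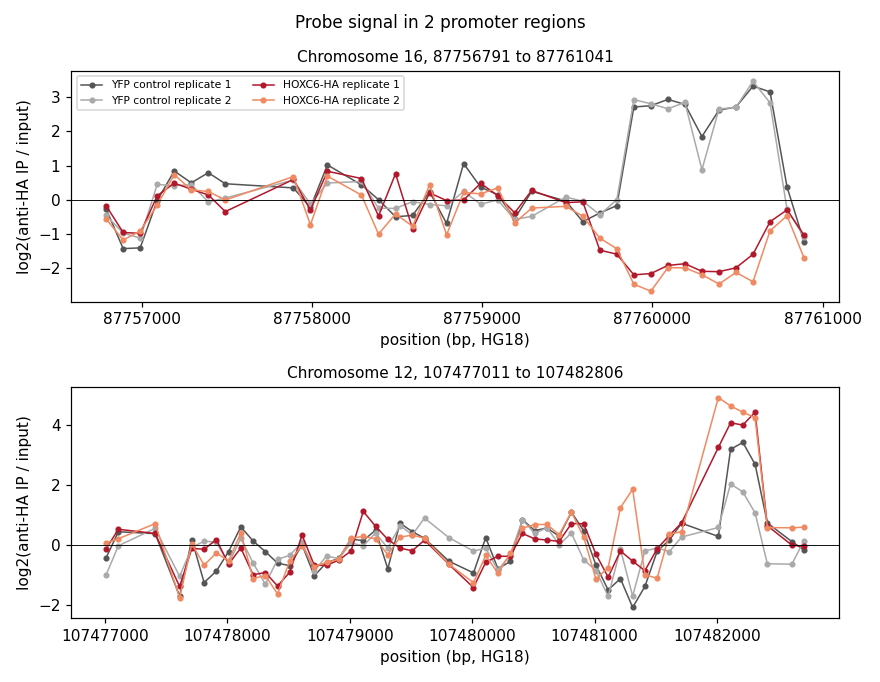
Log2 ratio of IP over input per probe (vertical axis) by position on HG18 (horizontal axis, bp) in the 4 samples, in the region on chromosome 16 with the lowest moderated t and in the region on chromosome 12 with the highest peak-shaped signal of the HOXC6-HA pair. On chromosome 16 both YFP control samples rise over a run of neighbouring probes where both HOXC6-HA samples dip, and on chromosome 12 the peak stands in both HOXC6-HA samples and, lower, in both YFP control samples.

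Samples of one group were not in every case more alike than samples of different groups. On array 1, Pearson's r of the probes' log2 ratio was 0.715 between the YFP control samples and 0.818 between the HOXC6-HA samples, and it was 0.818 between YFP control 1 and HOXC6-HA 1. On array 2 the values were 0.538, 0.750 and 0.720. YFP control 2 with HOXC6-HA 2 had the lowest r of all pairs on array 1, at 0.619. On array 2 the lowest r, 0.538, was that between the YFP control samples. Probes are not independent replicates. The input channel agreed better between samples than the IP channel, with r from 0.862 to 0.956 against 0.561 to 0.804 on array 1 and from 0.789 to 0.904 against 0.306 to 0.614 on array 2.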

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

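No named region changed sign under any alternative, but some alternatives could not reverse a difference. The 2 variance models and the replicate number as a block leave the difference as it was. Leaving out 1 sample cannot reverse it where the groups do not overlap, as in the 15 highest and 10 lowest regions by moderated t. From 0 higher and 0 lower regions, the counts moved to 1 lower with normexp, 1 lower with loess, 2 higher and 13 lower with quantile normalization, 4 lower with an intensity trend, and 30 higher and 626 lower single probes of 757904, in 28 and 389 regions. With the replicate number as a block there were 5 higher and 9 lower regions and 1 HOXC6-specific region. Deviations from the group mean of equally numbered samples correlated at -0.127 on array 1 and 0.196 on array 2 (-0.011 over both), so equal numbers were not taken as pairs. YFP control 1 and HOXC6-HA 1 were nevertheless about as alike over regions as the HOXC6-HA samples. Pearson's r was 0.928 and 0.913 on the 2 arrays against 0.920 and 0.907. Spearman's correlation was 0.921 and 0.895 against 0.926 and 0.897. YFP control 2 and HOXC6-HA 2 were less alike (Pearson's r of 0.814 and 0.771). A block with crossed numbers, chosen after seeing the data, gave 0 higher and 13 lower regions. Leaving out 1 sample in turn gave 0 to 11 higher, 0 to 22 lower and 0 to 7 HOXC6-specific regions; the lone sample of a group is then assumed to vary like the other group. The remaining alternatives gave 0 calls. Enriched regions, 2999 in HOXC6-HA and 2571 in YFP control, fell to 206 and 72 with loess, to 1730 and 1224 without the dimmest probes and to 0 and 239 with the best window of 5 probes, and ranged from 300 to 4039 and from 1651 to 2069 with a sample left out. The cause of these changes was not tested, beyond the fewer samples or probes that some of these settings use. The best window was picked for the highest mean over all samples, so its counts are no measure of enrichment. Regions with peak-shaped signal in HOXC6-HA, 134, became 80 with windows of 1000 bp, 311 at a window p of 0.001, 19 at 1e-06 and 242 with loess. The mirror count, 126, became 286 at 0.001 and 34 at 1e-06. With 1 sample left out the counts ran from 141 to 796 and from 134 to 870, since 1 condition fewer then applies. Of 525 values of named regions under 15 alternatives, 474 stayed on their side of the threshold, 40 differences came past it and 11 group means no longer passed. Splitting regions at gaps gave no value for the named regions. The tally counts the threshold only, and differences changed in size within it. The chromosome 17 region at 388444 moved from -1.32 to -0.3 with the median over probes and to -0.71 with the best window. In the same order, the chromosome 16 region at 87756791 moved from -1.26 to -0.67 and -3.87. The chromosome X region at 47745177 moved from 0.57 to 0.32 and 4.35, and the chromosome 21 contig region at 1383659 from 1.03 to 1.37 and 0.94. Gene lists, the HOXC6 locus and named genes were not run, for want of a gene annotation on HG18. Signal over background limits all of this: 15.8% of tiled probes exceeded the random probes' 95th percentile in the weakest IP.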

Other observations

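The tests in this part were chosen only after the results were seen. On the random contigs of chromosomes 4 and 21, which were looked at because 4 of their regions were among the highest differences, 6 of 8 regions were higher in both HOXC6-HA samples than in both YFP control samples, with differences over the 8 regions of 0.06 to 1.03 and a median of 0.87. Over all 44 regions on random contigs the median difference was 0.08, with 13 regions higher and 7 lower without overlap. Among 25 chromosome sets, these 44 regions formed the 1 set past the threshold (limma camera, adjusted p = 0.00316), and it did not pass with an estimated correlation (adjusted p = 0.977). The input signal of these contigs was high, with a median of 1.00 against 0.27 on chromosome 1, on the log2 scale relative to the median of the array.

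Short runs of raised probes stood in every sample. Runs of at least 3 neighbouring probes with a log2 ratio above 2 numbered 487 in YFP control 1, 619 in YFP control 2, 675 in HOXC6-HA 1 and 1109 in HOXC6-HA 2. Their median span was 200 bp in each sample, the shortest that 3 probes spaced 100 bp apart can have. The edges were steep, but part of the step is built in, since a run ends where the ratio is no longer above 2. The last probe inside had a median of 3.13 and the first probe outside, 100 bp away, a median of 0.18. Of 4495 ends, 84.1% lay below 1 in that first probe, and no reference share was computed. Binding of HOXC6-HA as the source of such runs in general is argued against by YFP control 2, where 96.1% of the runs had a mean ratio of 1.5 or less in both HOXC6-HA samples and 81.8% of their ends lay below 1. Amplification of single DNA fragments would give such edges and may be a source, but neither fragment length nor amplification is given in the sources used here, and binding at runs of the HOXC6-HA samples was not excluded.

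YFP control 1 held almost no run of its own: only 3 of its 487, or 0.62%, had a mean ratio of 1.5 or less over the same probes in all other samples, against 60.9% in YFP control 2, 11.7% in HOXC6-HA 1 and 70.7% in HOXC6-HA 2, while by the window test, which also takes weaker signal, 21.8% of its called regions were called in no other sample, against 74.6%, 29.9% and 73.5% in the same order. It shared 285 runs with HOXC6-HA 1, 157 with YFP control 2 and 29 with HOXC6-HA 2, while YFP control 2 shared 14 with HOXC6-HA 1 and 11 with HOXC6-HA 2, and the HOXC6-HA samples shared 116; with a threshold of 3 in place of 2 the first 2 numbers were 71 and 50. Loci that are raised in any chromatin would recur everywhere, but 7.8% of its runs were raised in all 4 samples, which argues against these. An exchange of labels between the groups would leave a pair with at most 14 shared runs, where the pairs as labelled had 157 and 116, but since the highest number, 285, stood across the groups, wrong labels were not excluded. A mixture in YFP control 1 of DNA that also reached YFP control 2 and HOXC6-HA 1 is a candidate explanation that these counts allow. In YFP control 1, 85.9% of the runs of HOXC6-HA 1 but 44.4% of those of YFP control 2 were above 1. Had YFP control 1 given its DNA as a whole to both, YFP control 2 and HOXC6-HA 1 would share its runs. They shared 14, against 157 and 285 with YFP control 1, which argues against that direction. Other routes and the step of such a transfer stay open.

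The fall of the ratio with input level, its own denominator, is the same fact as a slope below 1 of the IP on the input channel. That slope, in log2 of the mean signals, ran from 0.177 to 0.474 on the 8 arrays, over the 96.9% to 99.8% of regions with both signals above the median of the random probes. Binding of HOXC6-HA is argued against as the cause, since 41.7% of the regions in the lowest of 4 input bins were enriched in YFP control. After the median of the random probes was subtracted from both channels, the slope over the same regions was 0.295 to 0.875, higher by over 0.1 on 8 of 8 arrays, with a median of 0.656 against 0.372 before. Subtracting a constant close to the signal stretches its log2 scale, and the random probes lay closer to the tiled probes in the IP channel. In YFP control 1 on array 1 their medians were 946.6 and 1066 in IP and 394.9 and 719.9 in input. Such a subtraction raises the slope by itself, so the rise cannot decide whether an additive background in the IP signal causes the fall. The slope stayed below 1, and noise in the input signal and base composition were not tested.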
